A study of Homo sapiens with 9 samples.

How the data were processed

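Gene expression was measured by RNA sequencing in cultures that the labels assign to MDA-MB-231, an established human cell line derived from a triple-negative breast cancer. The labels describe 9 samples in 3 groups of 3: small spheroids, large spheroids and capsules. Per the labels' protocols, the cells were kept in RPMI medium with 10% fetal bovine serum, and RNA was taken with TRIzol after 96 h and made into libraries with Illumina's TruSeq protocol. The labels give every sample, the capsules included, the same treatment text, which names liquid overlay, 5% Matrigel and trastuzumab, an antibody against the receptor ERBB2.

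The deposited values were counts of reads per gene, whole numbers with no normalization, for 17911 Entrez gene IDs in 9 columns. Per the submitters' processing notes, the build was hg38 and the tools included featureCounts and limma, with no version or role given. The aligner, the annotation and the strand setting were not given in the sources used here. Because strand handling was not stated, reads of overlapping and antisense genes cannot be separated, and reads of near-identical copies such as ribosomal protein pseudogenes may have been split between them.

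Samples were matched to columns by name only. The 3 capsule columns each matched 1 sample. The 6 other columns of counts have names that fit both the small and the large spheroid samples and give no size, so they were matched to no sample and not used in any step. No comparison between groups was made. Capsules were not compared with a pool of all spheroids either. By the rule used here, a column entered only where its name matched 1 sample or 1 group, and none of the 6 did. The 8 tests planned before the data were examined (differential expression with edgeR and gene list tests between capsules, small spheroids and large spheroids), and the 56 other settings set out for them, were not run. What follows describes the 3 libraries labelled capsule, and every setting reported was chosen after the data had been seen.

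Counts were scaled by the library total to CPM (counts per 1e6 counts). The totals were 13212665, 13735221 and 13596073 for replicates 1, 2 and 3. A gene at 0 counts in a library is compatible with up to 3 counts, which equals 0.227, 0.218 and 0.221 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Values are means ± SD over the 3 libraries. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

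The spread between libraries was estimated with edgeR 4.0.16 in R 4.3.3 as the common biological coefficient of variation, after TMM scaling and edgeR's default filter on low counts. Differences beyond counting noise were tested per gene by a chi-square test of the 3 counts against the library totals, for genes with at least 30 counts over the 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares libraries, not conditions. On simulated Poisson counts with the real means and totals, it found 96 of 100 genes changed 1.5-fold in 1 library and 54 of 100 changed 1.2-fold, with 8 false calls among 15292 genes tested. The changed genes were drawn only from genes with counts well above the minimum of 30. Recovery among genes near that minimum was therefore not measured. With a simulated spread of 10% between 3 libraries, edgeR returned 9.98% over 14788 genes. A correction for GC content and exon length took library offsets from 10 bins of each property. On simulated counts with a GC trend in 1 library it lowered the calls from 2968 to 0 of 15297 genes. A trend with length was not simulated. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

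A set of 41 gene lists and 7 genes (ERBB2, EGFR, VEGFA, CA9, MKI67, VIM and CDH1) was fixed before the data were examined. The rest of the rule for named genes rested on comparisons between groups and was not applied. All other genes were chosen after their values were seen, mostly as the 3 most abundant members of a list or the 10 most abundant genes. A list's level is the median CPM of its members in each library, and its rank is the percentile of its median among 10000 random lists of the same size. Ranks were also computed after division by exon length from GENCODE release 29, known for 17131 genes (95.6%). That length joins the annotated exons of all transcripts of a gene, so it can exceed the length of the mRNA expressed. Ratios and ranks per kilobase are therefore approximate. Coordinates were taken by Entrez ID from the RefSeq annotation of GRCh38.p14, the assembly that hg38 denotes, for the 17667 IDs that matched.

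Background lists of 25 genes abundant in MDA-MB-231 and 10 genes abundant in HEK293, an established human embryonic kidney line with neuronal features, were written from general knowledge after a first look at the data. Alternatives were other CPM levels, other scalings (TMM, median-of-ratios size factors, library totals only), other count minimums, the correction for GC content and length, and leaving out each library in turn. The gene XIST and Y-linked genes were kept out of the named genes, the gene lists and the random lists. Library totals, shares of all counts, the spread between libraries and the counts of genes detected or differing were computed over all rows, these included.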

Results

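RNA sequencing profiles were examined for the 3 libraries labelled capsule, 1 of the 3 groups of MDA-MB-231 cultures that the labels describe. The series title sets small spheroids beside capsules, which points to a comparison of culture formats. That comparison was not made, because the other columns of counts could not be tied to samples. The profiles below therefore describe levels within the capsule group. Several abundant and scarce genes go against the MDA-MB-231 label, as described further on, so the samples are named by their label throughout.

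Between 17462 and 17488 genes had at least 1 count in a library, and 14227 genes reached 1 CPM in all 3. No count was found in any of the 3 libraries for 208 genes. Mitochondrially encoded mRNAs took 3.30% ± 0.110 (SD, n = 3) of all counts and mitochondrial ribosomal RNAs 0.802% ± 0.0743 (SD, n = 3). The 10 most abundant genes together took 4.71% ± 0.0376 (SD, n = 3). Pearson's r of log2(CPM + 0.5) across 15279 genes, which are not independent replicates, was between 0.994 and 0.995 for the 3 pairs of libraries. No pair agreed within counting noise, with at least 1203 genes differing in each, so none was taken for a library deposited more than 1 time, although repeat preparations of the same RNA can also differ.

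Genes of translation, mitochondria and glycolysis were the most abundant. COX1, the mitochondrially encoded cytochrome oxidase subunit, was at 8107 ± 84.9 CPM (SD, n = 3), and EEF2, the translation elongation factor, at 5628 ± 357 CPM. Ribosomal proteins had a median of 1357 ± 84.1 CPM over 30 genes, with RPS3 at 2979 ± 203 and RPS6 at 2864 ± 68.1 CPM. The processed pseudogene RPL13AP5 was listed at 3625 ± 234 CPM, and its reads may include those of its parent gene, which was not examined. The 13 mitochondrially encoded mRNAs had a median of 2465 ± 126 CPM. Nuclear genes of oxidative phosphorylation (26 genes) had a median of 177 ± 8.28 CPM, and genes of ribosome biogenesis and MYC targets (24 genes) one of 244 ± 5.23 CPM, led by the nucleolar protein NCL at 1759 ± 86.8 CPM. Each of these 4 lists ranked above all 10000 random lists, with and without division by exon length.

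All 20 genes of glycolysis and glucose uptake reached 1 CPM in every library, with a median of 208 ± 13.3 CPM (SD, n = 3). The glycolytic enzymes GAPDH and ENO1 were at 3509.9 ± 148 and 3213 ± 137 CPM. LDHB, which encodes the heart-type lactate dehydrogenase subunit, exceeded LDHA, the muscle-type subunit, by 1.45-fold in CPM, in 3 of 3 libraries. The ratio was 3.02-fold after division by exon length. The joined exons were 6210 bp for LDHA and 2983 bp for LDHB, so the larger ratio rests on the annotation. The hypoxia list had a median of 45.1 ± 1.49 CPM, and 21 of its 25 members reached 1 CPM in all libraries. Its members spread widely. NDRG1 was at 501 ± 24.8 CPM and STC2 at 314 ± 1.33 CPM, whereas CA9, the hypoxia-induced carbonic anhydrase, was at 0.445 ± 0.390 CPM, with 8, 10 and 0 counts. The list's rank of 98.7 among random lists became 84.5 after division by exon length.

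Genes of the cell cycle were abundant. The 28 genes of S phase and DNA replication had a median of 149 ± 3.83 CPM (SD, n = 3), and the 26 genes of G2 and mitosis one of 137 ± 6.67 CPM, and every member of both lists reached 1 CPM in all libraries. MCM7, a subunit of the replicative helicase, was at 888 ± 42.6 CPM, TOP2A, the mitotic topoisomerase, at 536 ± 47.2 CPM, and MKI67, the proliferation marker, at 485 ± 28.0 CPM. Targets of p53 had a median of 35.2 ± 1.32 CPM over 20 genes, with CDKN1A, the cyclin-dependent kinase inhibitor, at 43.4 ± 3.38 CPM. Apoptosis regulators had a median of 31.7 ± 1.63 CPM over 23 measured genes, led by the survival factor MCL1 at 211 ± 2.01 CPM.

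Genes of stress responses and lipid synthesis were abundant, apart from the metallothioneins. The amino acid response list had a median of 151 ± 1.31 CPM (SD, n = 3), with its regulator ATF4 at 996 ± 8.85 CPM. The unfolded protein response list had a median of 145 ± 6.24 CPM, with the chaperones CALR at 999 ± 13.8 and HSPA5 at 832 ± 12.4 CPM. Heat shock genes had a median of 209 ± 13.1 CPM, led by HSP90AA1 at 2531 ± 191 CPM. Cholesterol synthesis genes had a median of 89.1 ± 1.18 CPM, and fatty acid synthesis genes one of 63.6 ± 0.835 CPM. The latter had a rank of 99.5 among random lists (94.6 per kilobase), with the fatty acid synthase FASN at 1139.7 ± 80.2 and the desaturase SCD at 1045 ± 38.0 CPM. Autophagy and lysosome genes had a median of 61.7 ± 2.23 CPM. NRF2 targets had a lower median of 40.6 ± 1.35 CPM and a rank of 96.0 (98.65 per kilobase). The 5 measured metallothionein and zinc genes had a median of 15.3 ± 1.09 CPM, a rank of 48.6 among random lists.

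Genes of the interferon response and of NF-kB signalling were scarce. The 28 interferon response genes had a median of 1.45 ± 0.240 CPM (SD, n = 3), a rank of 0.04 among random lists, and 14 reached 1 CPM in all libraries. IFIT1, an interferon-induced gene, was at 4.26 ± 1.2 CPM. NF-kB targets and cytokines had a median of 2.10 ± 0.473 CPM over 23 measured genes and a rank of 0.47, with the cytokine IL6 at 0.0497 ± 0.0431 CPM, under the floor of 3 counts, and CXCL8 at 0.664 ± 0.333 CPM. MHC class I genes had a median of 6.85 ± 0.858 CPM and a rank of 13.8 (4.17 per kilobase), led by HLA-C at 196 ± 11.5 CPM. HLA genes vary between genomes, and reads that differ from the reference can be lost or assigned to a related gene. AP-1 and immediate early genes lay near the middle, with a median of 18.5 ± 1.51 CPM and a rank of 55.6 (65.0 per kilobase), led by JUN at 638 ± 9.26 CPM.

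The mesenchymal marker VIM, an intermediate filament gene, was at 339 ± 6.26 CPM (SD, n = 3) and the epithelial adhesion gene CDH1 at 9.41 ± 0.767 CPM. The ratio of VIM to CDH1 was 36.2 ± 3.01 (43.2 after division by exon length), and VIM was higher in 3 of 3 libraries. CDH2, the neural cadherin, exceeded CDH1 by 6.56-fold ± 0.873 (8.12-fold after division by exon length). All 21 mesenchymal genes reached 1 CPM in every library, with a median of 22 ± 2.08 CPM. Their rank among random lists was 62.4 (38.5 per kilobase), so the list as a whole was not high. Epithelial and luminal genes had a median of 5.61 ± 0.166 CPM over 26 measured genes and a rank of 4.73 (3.87 per kilobase). XBP1 led this list at 230 ± 23.4 CPM. The simple keratin KRT8 was at 98.2 ± 2.19 CPM and the adhesion molecule EPCAM at 4.74 ± 0.757 CPM. VIM exceeded KRT8 by 3.45-fold ± 0.0154 (4.61-fold after division by exon length), far less than it exceeded CDH1. Basal and squamous genes had a median of 1.75 ± 0.161 CPM over 11 measured genes. Both genes of a ratio were measured in the same 3 libraries, where an exact sign-flip permutation test cannot go below p = 0.25 (two-sided), so such differences were described by their ratios.

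Lists of matrix, adhesion and cytoskeletal genes had different ranks among random lists. Extracellular matrix genes had a median of 18.8 ± 1.49 CPM (SD, n = 3) and a rank of 57.7, which became 3.04 after division by exon length. The laminin chain LAMC1 was at 171 ± 12.4 CPM and the collagen chain COL6A1 at 170 ± 21.1 CPM. Matrix remodelling enzymes had a median of 10.3 ± 0.794 CPM, with a rank of 20.9 (12.2 per kilobase), led by the protease ADAMTS1 at 267 ± 5.46 CPM. Actin and SRF targets had a median of 90.6 ± 0.711 CPM and a rank of 100 (99.7 per kilobase), and integrins and focal adhesion genes one of 27.6 ± 1.16 CPM and a rank of 83.6 (55.8 per kilobase). YAP and TAZ targets had a median of 13.6 ± 1.51 CPM and a rank of 36.1 (12.8 per kilobase), and TGF-beta targets one of 18.8 ± 0.557 CPM and a rank of 56.5 (47.1 per kilobase). CCN2, a YAP target, was at 3.28 ± 0.386 CPM.

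ERBB2, the receptor that trastuzumab binds, was at 137 ± 6.64 CPM (SD, n = 3), and EGFR, its relative, at 13.6 ± 2.52 CPM. ERBB2 exceeded EGFR by 10.2-fold ± 1.5, in 3 of 3 libraries, and by 12.2-fold after division by exon length. ERBB3 was at 9.39 ± 1.49 CPM and the ligand NRG1 at 0.220 ± 0.144 CPM. The list of ERBB family genes and ligands also held other genes, among them STARD3 and the feedback inhibitor ERRFI1. Its 14 measured members had a median of 5.64 ± 0.273 CPM. VEGFA, the angiogenic growth factor, was at 72.7 ± 3.06 CPM, against a median of 2.99 ± 0.726 CPM for angiogenic and growth factors. Drug efflux transporters had a median of 4.71 ± 0.266 CPM and breast cancer stem cell markers one of 9.78 ± 1.24 CPM. On hg38, ERBB2 (Entrez 2064) lies on chromosome 17 from 39688094 to 39728658 and EGFR (Entrez 1956) on chromosome 7 from 55019017 to 55211628. VEGFA (Entrez 7422) lies on chromosome 6 from 43770211 to 43786487, and VIM (Entrez 7431) on chromosome 10 from 17228241 to 17237593.

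**Figure D1:**
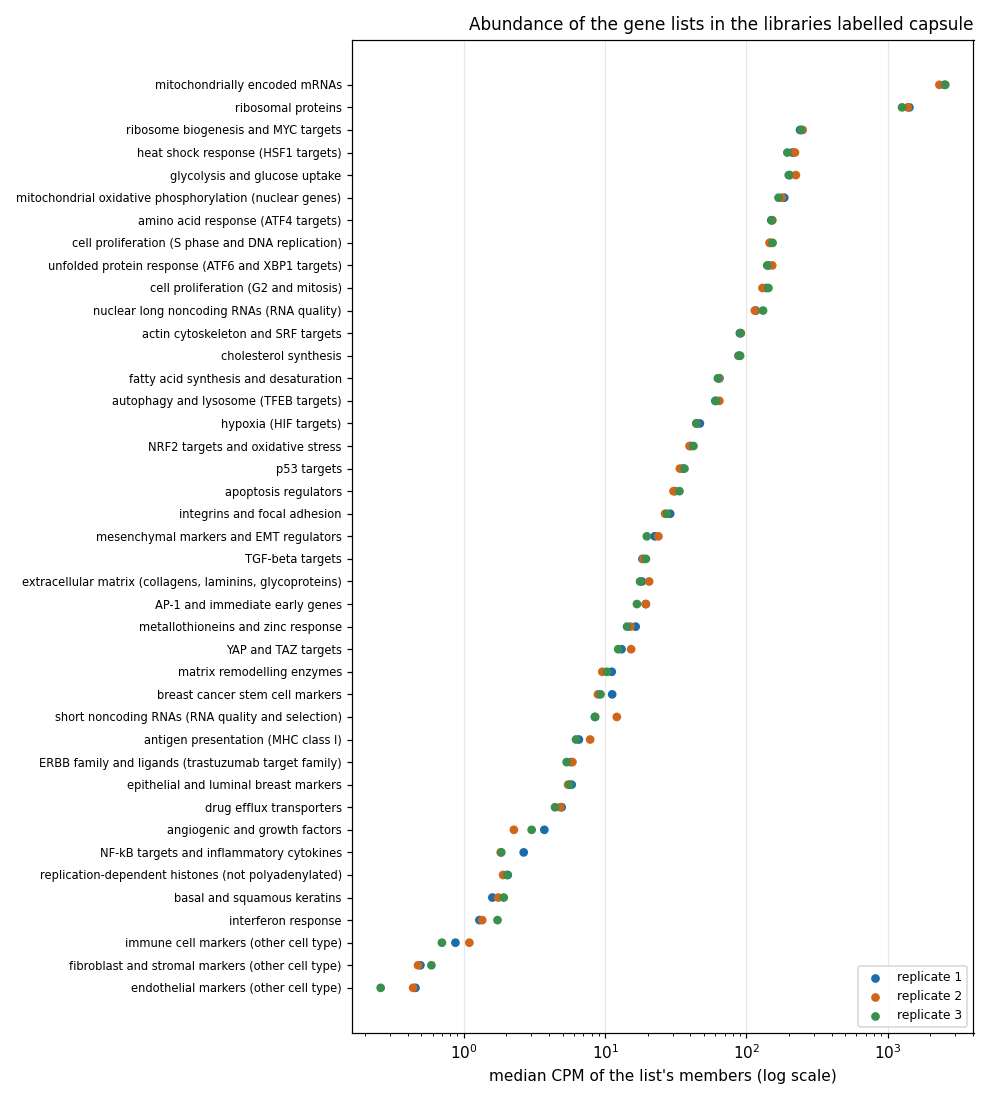
Median CPM of the members of each gene list (log axis), with 1 point per library labelled capsule and lists ordered by their mean. Mitochondrially encoded mRNAs (2465 CPM) and ribosomal proteins (1357 CPM) lie highest, and the endothelial markers lie lowest (0.383 CPM).

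Markers of other cell types were near the detection limit. Medians were 0.887 ± 0.197 CPM for immune markers, 0.518 ± 0.0618 CPM for fibroblast and stromal markers and 0.383 ± 0.109 CPM for endothelial markers (SD, n = 3). FBLN1 at 73.2 ± 4.04 CPM and COL1A1 at 38.9 ± 1.79 CPM stood above the other fibroblast markers. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had a median of 1.99 ± 0.0816 CPM, led by H2BC12 at 107 ± 0.422 CPM. Their rank of 0.12 became 23.0 per kilobase. Short noncoding RNAs had a median of 9.67 ± 2.09 CPM, led by RN7SL2 at 1131 ± 160 CPM, and their rank of 27.0 became 100 per kilobase. Nuclear long noncoding RNAs had a median of 121 ± 8.99 CPM and a rank of 99.6 (64.3 per kilobase), with MALAT1 at 468 ± 75.3 CPM. Of the 41 lists, 15 ranked at or above the 99th percentile of random lists, 13 of them also per kilobase, and 6 at or below the 1st percentile, 4 of them also per kilobase.

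Several genes that MDA-MB-231 cells are known to express abundantly were scarce. CD44, the hyaluronan receptor, was at 2.20 ± 0.327 CPM (SD, n = 3), AXL, a receptor tyrosine kinase, at 0.818 ± 0.357 CPM and ANXA1, a phospholipid-binding protein, at 5.16 ± 0.137 CPM. Of the 25 genes on this background list, 13 lay under the 50th percentile of all genes and 9 under 5 CPM, and the list ranked at 37.1 among random lists (43.6 per kilobase). CAV1, the caveolar coat protein, lay near the middle at 16.8 ± 2.03 CPM. Another 5 lay in the top 10%, among them VIM, AKR1B1 and GSTP1, with AKR1B1 at 307 ± 17 CPM and GSTP1 at 306 ± 19.4 CPM. CDKN2A, the cell cycle inhibitor locus that is deleted in MDA-MB-231, was at 524 ± 43.8 CPM with at least 6436 counts in each library. It has Entrez ID 1029 and lies on chromosome 9 from 21967752 to 21995324. Its neighbour CDKN2B, also deleted in that line, was at 19.2 ± 1.15 CPM. The neuronal intermediate filament NEFM was at 438 ± 21.5 CPM, the creatine kinase CKB at 1411 ± 114 CPM and the RNA-binding protein LIN28B at 56.8 ± 2.84 CPM.

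**Figure D2:**
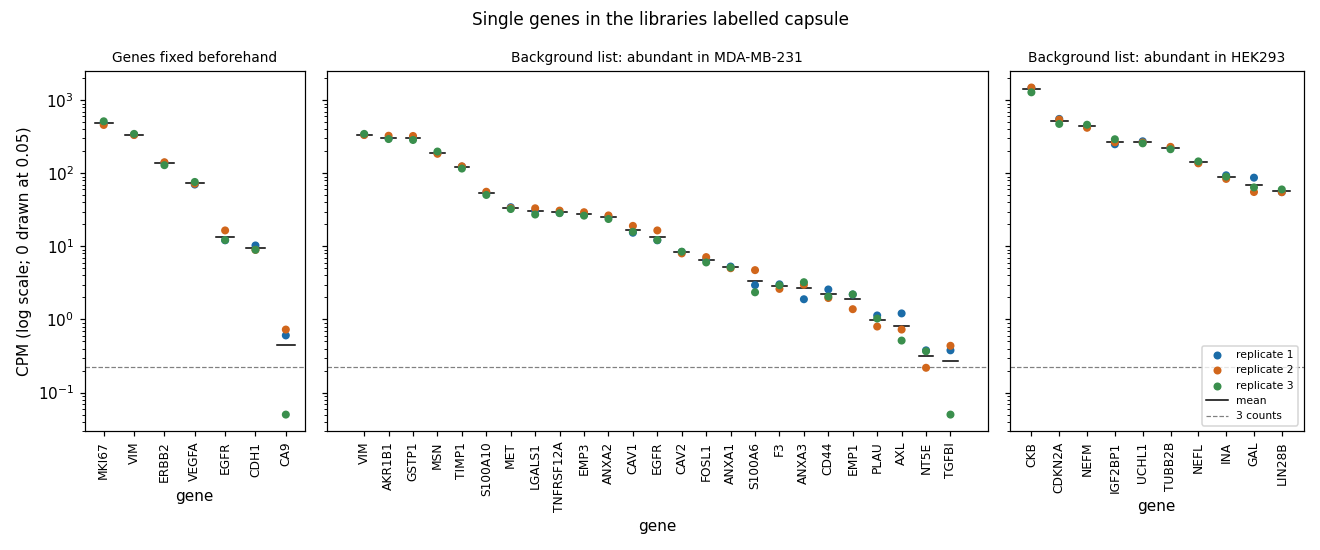
CPM per library (log axis, a value of 0 drawn at 0.05) for the 7 genes fixed beforehand, 25 genes known to be abundant in MDA-MB-231 and 10 known to be abundant in HEK293. Points are the 3 libraries labelled capsule, black lines their means and the dashed line the level of 3 counts. CDKN2A lies at 524 CPM and CD44 at 2.20 CPM.

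The 3 libraries differed in many genes, and the test of counts finds smaller differences in more abundant genes. Among ribosomal proteins, 29 of 30 differed beyond counting noise, also when adjusted over the list alone, and 28 of these were lowest in replicate 3. Their median range between libraries was 0.19 on the log2 scale. All 13 mitochondrially encoded mRNAs differed, also when adjusted over the list alone, and 11 were lowest in replicate 2 (9 after correction for GC content and length). Of the G2 and mitosis genes 16 of 26 differed, also adjusted over the list alone, and 12 of them were lowest in replicate 2. After the correction 6 differed, 4 of them lowest in replicate 2. Of 6 nuclear long noncoding RNAs 4 differed, all lowest in replicate 2 as well, and after the correction 2 differed, again lowest there. Among the differing genes at 5 CPM or more, the widest ranges were those of the casein kinase CSNK1E at 8.30 ± 4.41 CPM (SD, n = 3), which differed 3.16-fold between its highest and lowest library, SUSD2 at 18.2 ± 7.97 CPM (2.66-fold) and C4orf48 at 18.2 ± 10.3 CPM (2.51-fold). edgeR's common biological coefficient of variation was 6.01%. In all, 3183 of 15279 genes (20.8%) differed beyond counting noise, with a median range of 1.2-fold and 311 of them with a range of 1.5-fold or more. This count was 1375 after the correction for GC content and length, and 1302 without replicate 2 and 1203 without replicate 3.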

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

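All settings in this part were chosen after the data had been seen. None of the 56 settings set out before the data were examined was run, since they belong to comparisons between groups that were not made. No paired analysis was possible because only the columns of 1 group could be matched to samples, so no groups shared replicate numbers. The count of genes at 1 CPM in all 3 libraries, 14227, was 15358 at 0.5 CPM and 11583 at 5 CPM, and ranged from 14349 to 14417 when a library was left out. The biological coefficient of variation, 6.01%, lay between 6.02% and 6.04% under other scalings and without a filter, and ranged from 5.15% (without replicate 3) to 7.32% (without replicate 1). The count of genes differing beyond counting noise, 3183, was 3127 with TMM, 3125 and 3217 with other count minimums, and 1375 with the correction for GC content and length, which by its construction removes differences that follow those properties. Leaving out a library gave 1203 to 2861 genes, with fewer libraries in the test. Of 43 list ranks, 14 moved by over 1.5 times when counts were divided by exon length. A ratio of ranks weighs low ranks most. It counted the interferon list as moved (0.04, then 0), but not the integrin and focal adhesion list (83.6, then 55.8). The count of 14 therefore does not measure how far the ranks depend on length. With TMM, all 44 list medians and 222 named genes stayed within their SD. The TMM factors were 0.993, 0.996 and 1.01 for replicates 1, 2 and 3, so they could hardly move a mean over the libraries. Leaving out a library cannot move a mean of 3 by more than its SD, so that check says nothing about stability. Depth limits genes such as CA9 and IL6, which had 10 counts or fewer per library.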

Other observations

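Tests on CDKN2A were set out before its level was seen. All other tests in this part were chosen after the values that prompted them.

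The 3 libraries labelled capsule did not have high levels of genes known as abundant in MDA-MB-231, whose 25-gene list had a median percentile of 46.7 among all genes. Gene length, as measured by the joined exons, was argued against as the whole cause by a median percentile of 48.3 per kilobase. A change of state of MDA-MB-231 cells alone was argued against by CDKN2A, since a deleted gene gives no reads and the lowest library held 473 CPM. That value is consistent with cells other than MDA-MB-231, through a wrong label or an exchange of samples, and a mixture of cells stays open. Cells of the HEK293 type are a candidate source. Their 10-gene list had a median percentile of 96.4, and 93.9 for 8 genes without CKB, which prompted the list, and CDKN2A. The whole list was written after a first look at these data, so the 8 genes are not an independent check. Such genes also do not single out a cell line, and no biological explanation from the groups was tested.

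Ribosomal protein genes moved together between the 3 libraries, with medians of 0.04, 0.05 and -0.11 (log2, relative to each gene's mean) in replicates 1, 2 and 3. Other lists also had medians under 0 in replicate 3, among them metallothioneins (-0.10), AP-1 and immediate early genes (-0.09), epithelial and luminal genes (-0.07), MHC class I genes (-0.07) and nuclear oxidative phosphorylation genes (-0.05). Markers of other cell types did too, with -0.20 for immune and -0.06 for fibroblast markers. Each of those lists had only 4 genes tested, and the 1 differing immune marker was highest in replicate 3. Whether the shift was shared was not tested. GC content and joined exon length as the whole cause were argued against by a median range of the ribosomal genes of 0.18 after the correction, against 0.19 before. The correction lowered the count of differing genes from 3183 to 1375. It cannot decide about the length of the expressed mRNA, which was not measured. RPS3, for example, had 5894 bp of joined exons. A different scale factor would move all genes alike. It was argued against by the gap in replicate 3 between the ribosomal genes (-0.11) and the 2275 other genes at 100 CPM or more. Those other genes had a median of -0.0026 (quartiles -0.06 and 0.05). Scaling to library totals largely fixes the median of abundant genes, so only the gap, not that median alone, bears on the question. Nuclear long noncoding RNAs went the other way, with a median of 0.20 in replicate 3 (0.10 after the correction) and 4 of 6 genes differing, all highest there (2 after it), as did short noncoding RNAs after the correction, with a median of 0.17 (0.06 before) and 5 of 5 differing genes highest there (2 of 5 before), whereas mitochondrially encoded mRNAs had medians of 0.01, -0.07 and 0.05 (-0.01, -0.03 and 0.04 after it). A difference in RNA handling or library preparation stays open, since the labels give no batch, and no biological explanation was tested.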
